A study of Mus musculus with 16 samples.

How the data were processed

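RNA from mouse hearts, 16 samples in 4 groups of 4 (Sham and 2, 4 or 10 weeks after the valve injury that causes aortic regurgitation), had been extracted with TRIzol and made into NEBNext Ultra libraries, per the labels' protocols. The deposited table holds a read count for each of 54532 Ensembl gene IDs in each of 16 sample columns. Its values are whole numbers of 0 or more with unequal column totals, which is what raw counts show, and no normalization by the authors was found in them. The reads had been aligned with HISAT2 2.0.5 to the mouse genome mm10, per the submitters' processing notes. The counting tool, the annotation release, the use of strand and the handling of reads with several matches are not given in the sources used here, nor are sex or batch. Values of genes with near-identical copies, or with other genes overlapping their exons, are therefore uncertain. The Sham labels give no week. The AR-2W samples have later record numbers than the other groups. Whether they were processed separately is not given, so such a difference cannot be told apart from an effect of the week.

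Gene IDs were matched to symbols by ID, which named 54409 of them and left 123 without a symbol. Positions and exon overlaps came from an annotation of the same genome build. Of all IDs, 25094 had 0 counts in every library. The edgeR function filterByExpr, with its default minimum count of 10 and minimum total of 15, kept 14947 genes, which held 99.9% of all counts. Library totals ran from 15642761 to 18131187. Libraries were scaled by TMM, and CPM values are counts divided by those scaled sizes and multiplied to a common total, with a prior count of 2 on the log2 scale. Intervals and exact tests on shares of counts cover counting error or the spread of these libraries only.

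Genes were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. All 16 libraries entered 1 model with a mean for each group, so that the groups shared an estimate of the spread (12 residual degrees of freedom, common coefficient of variation 16.7%). The 5 comparisons were each week against Sham, 4 against 2 weeks, and 10 against 4 weeks. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Standard errors were the log2 fold change divided by the square root of the F statistic. The words rose and fell are used for genes past that threshold.

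The gene lists, 45 of them, were fixed along with the comparisons, tests and most alternatives before the data were examined. Each was tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 45 lists of a comparison, and again with a correlation estimated for each list. No list call at the preset correlation held with the estimated one in any of the 5 comparisons. List means per library are given relative to the average of the 4 Sham libraries, on the log2 scale. The share of beta myosin heavy chain counts and 4 library measures were compared by two-sided exact permutation tests, which with 4 against 4 libraries can give no p below 0.0286. Overlap of calls was set beside 20 simulations of unchanged groups, beside independent lists of the same sizes, and beside splits of the Sham libraries.

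Genes were named by a rule. For each comparison with Sham it took the 10 largest rises and the 10 largest falls among genes past the threshold, with a mean log2 CPM of at least 1 and no overlap between the 4 values of each group, which 2 of the 70 assignments of 8 libraries give by chance. For the other 2 comparisons it took 5 and 5. Clone-named and predicted genes were passed over. A panel of 12 stress and matrix genes was reported at every week, and of each list described up to 4 members with the smallest p.

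The scripts were tested on simulated counts for the tested genes with 200 changed genes. For AR-10W minus Sham, with 14737 genes in the step, 30.8% of genes changed by 0.5 log2 units were recovered, 67.7% of those changed by 1 and 92.3% of those changed by 2, and 6.06% of calls were false. For AR-2W minus Sham the shares were 35.8%, 76.1% and 93.8%, with 7.48% false among 14755 genes. They were 34.3%, 72.3% and 96.9% for AR-4W minus Sham (7.64% false, 14749 genes), 36.9%, 71.9% and 95.3% for AR-4W minus AR-2W (7.75% false, 14750 genes), and 28.8%, 68.2% and 89.2% for AR-10W minus AR-4W (3.17% false, 14755 genes). In simulations over 14947 genes with no list changed, camera called 1 list in 20 runs of 45. Simulated genes were independent, so this says nothing about correlated lists.

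The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom, no filter and a stricter one, fits on the 8 libraries compared, a replicate block, library sizes without mitochondrially encoded genes, and leaving out each library. Those added after seeing the data left out the 3 libraries with over 200 Sln plus Myl7 counts, the 4 with over 100, or AR-2W replicates 1 and 2, or fitted the log2 CPM of Sln plus Myl7 (0.5 CPM added) as a covariate. No library was left out of the values reported first.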

Results

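Messenger RNA was measured by bulk RNA sequencing in hearts of C57BL/6J mice. In aortic regurgitation (AR) the aortic valve leaks, so blood flows back into the left ventricle and loads it with extra volume. Here the valve had been injured by minimally invasive surgery. Hearts were taken 2, 4 or 10 weeks later (AR-2W, AR-4W and AR-10W), and a Sham group, whose labels give no week, served as the control. Each of the 4 groups had 4 libraries, 16 in all, and no source used here says that replicates are separate animals, so p-values measure the spread between these samples. Total counts ran from 15642761 to 18131187 per library. The series design and the sample labels name the phases of disease differently at 4 weeks, so groups are described here by week only. The comparisons ask how heart gene expression differs from Sham at each week, and how it differs between successive weeks.

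A library trait that none of the group labels describes bears on every comparison. Sln and Myl7, which code for sarcolipin and a myosin light chain of atrial muscle, had 8990 counts together in Sham replicate 3, 1519 in AR-2W replicate 2 and 250 in AR-4W replicate 2. AR-2W replicate 1 had 105 and each other library 18 or fewer. The share of counts from mitochondrially encoded genes was 28.2% ± 1.38 (SD, n = 4) in Sham, 26.1% ± 1.20 in AR-2W, 26.7% ± 1.02 in AR-4W and 23.2% ± 3.00 in AR-10W. None of its 5 comparisons passed adjustment (two-sided exact permutation tests, smallest adjusted p = 0.190 over 20 tests, 4 library measures in 5 comparisons).

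At 2 weeks of AR Fabp5, a fatty acid-binding protein, rose from 30.5 ± 1.22 to 55.0 ± 5.77 CPM (counts scaled to library size, mean ± SD, n = 4), a log2 fold change of 0.85 ± 0.09 (SE, edgeR quasi-likelihood, adjusted p = 0.000522). Fabp5 (Ensembl ENSMUSG00000027533) lies at 10012548 to 10016607 on chromosome 3 of mm10. Eln, which codes for elastin, rose by 1.36 ± 0.25 (edgeR adjusted p = 0.0349), and Sparc, a collagen-binding matricellular protein, rose by 0.96 ± 0.20 (edgeR adjusted p = 0.0425). Aox1, aldehyde oxidase, fell by 0.79 ± 0.11 and Synj2, a phosphoinositide phosphatase of membrane traffic, fell by 0.66 ± 0.09, both with an edgeR adjusted p of 0.00868.

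Of 14947 genes tested in AR-2W minus Sham, 33 rose and 42 fell in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Other large rises were those of Trim59 (1.94, a ubiquitin ligase), E2f1 (1.70, a transcription factor of the cell cycle), Kcne1 (1.68, a potassium channel subunit), Mest (1.40, an imprinted growth gene), Lgals9 (1.34, a galectin), C1qtnf6 (1.00, a secreted complement-like protein) and Ctla2a (0.87, a protease inhibitor). The other large falls were those of Abca12 (-1.18, a lipid transporter), Amy1 (-1.14, an amylase), Ano10 (-0.99, an ion channel), Calr3 (-0.80, a chaperone), Slc27a1 (-0.69, a fatty acid transporter), Deptor (-0.66, an mTOR inhibitor), Arhgap20 (-0.65, a Rho regulator) and Sec31b (-0.62, a vesicle coat protein). Counts for Amy1, Mest and Ctla2a are uncertain because their exons overlap other genes or near-identical family members. None of the 12 stress and matrix genes chosen beforehand was called: Nppb, a natriuretic peptide of strained muscle, differed by 0.63 ± 0.28 (edgeR adjusted p = 0.288) and Postn, periostin, by 1.77 ± 0.74 (edgeR adjusted p = 0.262).

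Among collagen and matrix structural genes, 2 of 35 rose at 2 weeks, Eln and the basement membrane collagen Col4a1 (0.71 ± 0.15), and 33 were not called; 17 rose adjusted over the list alone. The camera list test gave adjusted p = 2.9e-13, against adjusted p = 0.755 with an estimated correlation. The list mean lay 1.05 above the Sham average in Sham replicate 3 and 1.52 in AR-2W replicate 2, both rich in atrial transcripts. Of 35 cell cycle genes none was called over all genes and 23 rose adjusted over the list alone, with Cdk1, a mitotic kinase, at 1.63 ± 0.40 and Ccnb1, cyclin B1, at 2.24 ± 0.58. The list test camera gave adjusted p = 2.03e-12, and adjusted p = 0.755 with an estimated correlation. Replicate 1 of AR-2W stood at 1.97 on this list and the other AR-2W libraries between 0.33 and 0.66. Of 28 interferon-stimulated genes none was called over all genes and 25 rose adjusted over the list alone, including Isg15, a ubiquitin-like antiviral protein (2.26 ± 0.53). In camera the list had adjusted p = 5.93e-12, and adjusted p = 0.755 with an estimated correlation. AR-2W replicates 1 and 2 stood at 2.24 and 2.04 on this list, and replicates 3 and 4 at 0.01 and 0.32. None of 31 fatty acid oxidation genes was called, though all 31 had negative fold changes (camera adjusted p = 2.68e-07, and adjusted p = 0.755 with an estimated correlation). Sham replicate 3 stood at -0.39 on this list, below AR-2W replicates 1 and 3 at -0.26 and -0.16. AR-2W replicates 2 and 4 stood at -0.41 and -0.45.

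The 75 calls at 2 weeks depended on single libraries, being 2, 5, 265 and 1 without Sham replicates 1, 2, 3 and 4. The number was 6 and 15 without AR-2W replicates 1 and 2, 22 without AR-4W replicate 2, and 46 without AR-10W replicate 4. Fabp5 was the only gene of the 20 with the largest rises and falls under the naming rule that stayed called whichever of the 16 libraries was left out. Without the 3 libraries with over 200 Sln plus Myl7 counts, 17 genes rose and 8 fell, a choice made after the data were seen.

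At 4 weeks of AR Igkc, the constant region of the kappa antibody chain, rose from 0.542 ± 0.157 to 4.28 ± 1.26 CPM (mean ± SD, n = 4), a log2 fold change of 2.96 ± 0.36 (SE, edgeR adjusted p = 0.00166). Its counts are uncertain because antibody genes form a large family of similar sequences. Trem2, a lipid-sensing receptor of macrophages, rose by 1.30 ± 0.25 (edgeR adjusted p = 0.0238). Nr4a3 fell by 2.13 ± 0.40 (edgeR adjusted p = 0.0213) and Nr4a1, a nuclear receptor of the same family that responds to acute stimuli, fell by 1.97 ± 0.40 (edgeR adjusted p = 0.0281). Amd1, an enzyme of polyamine synthesis, fell by 0.92 ± 0.10 (edgeR adjusted p = 0.000998), with reads that retrocopies of the gene could share.

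In AR-4W minus Sham 118 genes rose and 114 fell in the edgeR test. The other large rises were Edn3 (1.63, an endothelin), Gpr34 (1.20, a microglia and macrophage receptor), Ccdc152 (1.19), Gpr160 (1.16, an orphan receptor), Myom3 (1.15, a sarcomere M-band protein), Upp1 (1.14, uridine phosphorylase), Mmp28 (1.10, a matrix protease) and Nabp1 (1.06, a DNA-binding repair protein). Ccdc152 overlaps the abundant gene Selenop on the opposite strand and its value is uncertain. The other large falls were Foxo6 (-1.73, a transcription factor), Col6a6 (-1.27, a collagen VI chain), Aldh1l2 (-1.20, a mitochondrial folate enzyme), Sned1 (-1.09, a matrix protein whose exons overlap Mterf4), Tbc1d10c (-1.04, a Rab regulator overlapped by another transcript), Ano10 (-1.04), Celsr2 (-1.01, a cadherin) and Gzmm (-0.96, a granzyme). None of the 12 stress and matrix genes was called: the smallest edgeR adjusted p was 0.116, for Ccn2 (1.67 ± 0.53), a growth factor of scar formation.

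Of 16 endothelial markers 5 rose, none fell and 11 were not called at 4 weeks, and 12 rose adjusted over the list alone. They included Vwf, von Willebrand factor (1.04 ± 0.20), Cldn5, a tight junction protein (0.68 ± 0.13), and Fabp4, a lipid chaperone of capillaries (0.60 ± 0.12). For this list camera gave adjusted p = 9.25e-07, and adjusted p = 0.647 with an estimated correlation. All 4 AR-4W libraries had positive list means, from 0.12 to 0.45, but Sham replicate 4, at 0.14, lay above AR-4W replicate 4, at 0.12. Among T, NK and B cell markers 2 of 8 rose, Igkc and the antibody heavy chain Ighm (0.96 ± 0.20), and 7 rose adjusted over the list alone. Camera gave adjusted p = 9.25e-07, and adjusted p = 0.126 with an estimated correlation, and the 4 AR-4W libraries stood between 1.30 and 1.57 on this list. Cspg4, a pericyte proteoglycan, rose by 0.69 ± 0.14 (edgeR adjusted p = 0.0286). It was the only one of 15 pericyte and smooth muscle markers called, while 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00391, and adjusted p = 0.647 with an estimated correlation). Heat shock genes had 2 of 15 called, the chaperone partner Dnajb1 (-1.07 ± 0.23) and the chaperone Hspa8 (-0.57 ± 0.13), both lower. Over that list alone 3 fell (camera adjusted p = 0.0378, and adjusted p = 0.717 with an estimated correlation). Of 29 nuclear-encoded respiratory chain genes none was called and 28 had negative fold changes, with a median of -0.18 (camera adjusted p = 5.91e-05, and adjusted p = 0.717 with an estimated correlation). Sham replicate 3 stood at -0.33 on this list, below AR-4W replicates 1, 2 and 4 at -0.11, -0.23 and -0.07. Only AR-4W replicate 3, at -0.39, lay below it.

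The 232 calls at 4 weeks became 10, 11 and 469 without Sham replicates 1, 2 and 3. They were 126, 14 and 20 without AR-4W replicates 1, 2 and 3, and 144, 131, 146 and 143 without AR-2W replicates 1 to 4. Igkc, Sned1, Celsr2 and Amd1 stayed called whichever library was left out. In a fit without the 3 libraries rich in Sln and Myl7, chosen after the data were seen, 13 genes rose and 9 fell.

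At 10 weeks of AR Myh7, the beta myosin heavy chain, rose from 144 ± 84.6 to 1595 ± 1124 CPM (mean ± SD, n = 4), a log2 fold change of 3.46 ± 0.61 (SE, edgeR adjusted p = 0.00439). Myh7 (Ensembl ENSMUSG00000053093) lies at 54970684 to 54994626 on chromosome 14 of mm10. Nppb rose by 1.75 ± 0.28 (edgeR adjusted p = 0.00247) and Ankrd1, a stretch-sensing repeat protein of the sarcomere, rose by 1.78 ± 0.38 (edgeR adjusted p = 0.00884). Nppa, the atrial natriuretic peptide, rose by 3.41 ± 1.06 (edgeR adjusted p = 0.0445), and Acta1, skeletal alpha actin, by 2.78 ± 0.83 (edgeR adjusted p = 0.0382). Sham replicate 3 had 368 CPM of Nppa and the other Sham libraries 8.46 to 34.1, so the size of the Nppa rise depends on Sham replicate 3. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 0.57 ± 0.15 (edgeR adjusted p = 0.0228).

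**Figure D1:**
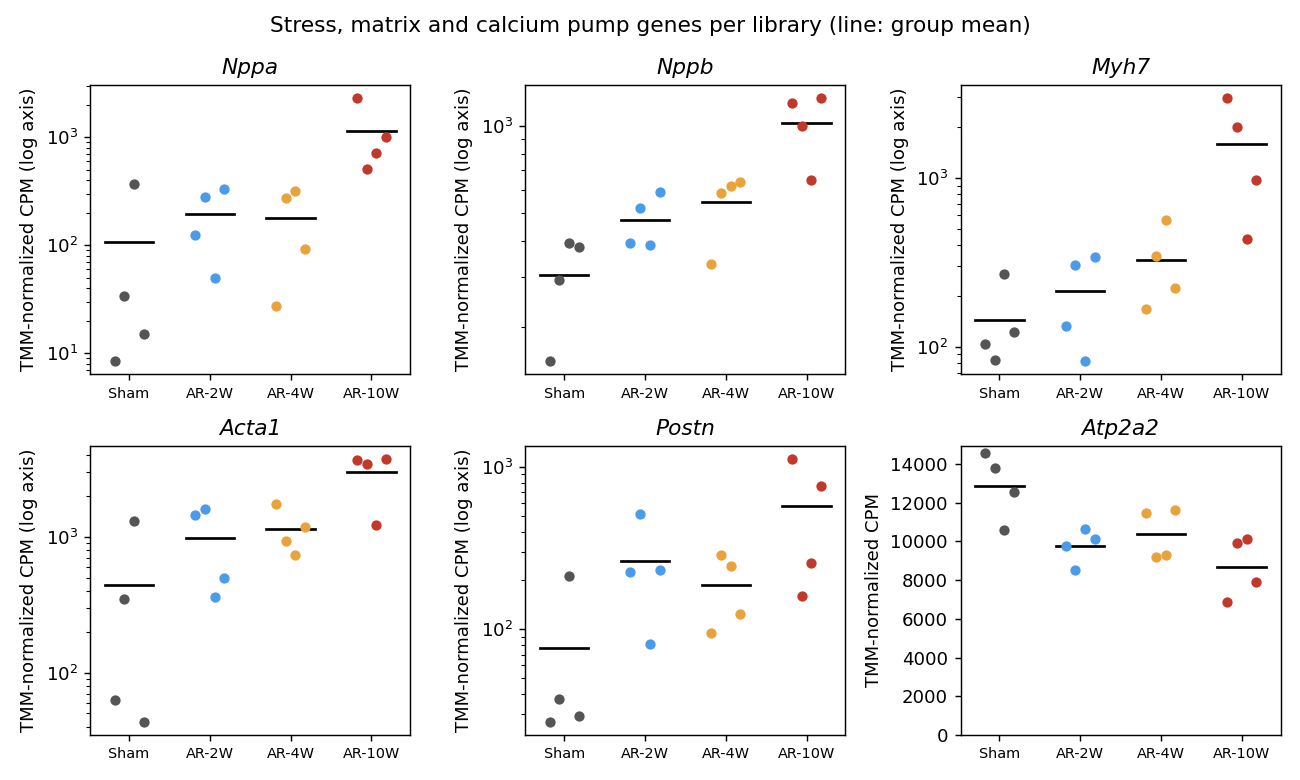
TMM-normalized CPM of 6 genes in each of the 16 libraries by group, on a log axis except for Atp2a2; points are libraries and lines are group means. Each AR-10W library lay above every Sham library for Nppa, Nppb and Myh7 and below every Sham library for Atp2a2, and Sham replicate 3 had 368 CPM of Nppa where the next highest Sham library had 34.1.

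In AR-10W minus Sham 921 genes rose and 973 fell in the edgeR test, 207 and 150 of them by at least 1 log2 unit. Apart from Myh7 and Nppa, the largest rises that met the naming rule, with no overlap between the groups, were Crlf1 (4.35, a cytokine receptor-like secreted protein), Pacsin1 (3.67, an endocytosis adaptor), Lman1l (3.25, a lectin), Gdf6 (2.67, a bone morphogenetic protein), Nmrk2 (2.51, a kinase of NAD synthesis), Col8a1 (2.28, a short-chain collagen), Vsig4 (2.25, a macrophage complement receptor) and Igkc (2.25). The largest falls that met the naming rule were Kcna2 (-2.99, a potassium channel), Acot1 (-2.29, a fatty acyl thioesterase), Ces1d (-2.15, a lipase), Tbc1d10c (-2.05), Plekhb1 (-1.97, a membrane adaptor), Col6a6 (-1.86), Foxo6 (-1.80), Adam23 (-1.79, an adhesion protein), Retnla (-1.77, a resistin-like protein) and Lgals4 (-1.73, a galectin). Acot1, Ces1d and Lgals4 belong to families of near-identical copies, so their counts are uncertain. Nppa is overlapped over 61.5% of its exons by an antisense gene, and the counting's use of strand is not known. The beta myosin share, Myh7 counts as a percentage of Myh6 plus Myh7 counts, was 0.944% ± 0.736 (SD, n = 4) in Sham and 11.6% ± 8.83 in AR-10W. It was higher in 4 of 4 AR-10W libraries (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give, and 0.143 after adjustment over 5 comparisons). AR-10W replicate 1 had 23.4% and replicate 3 had 3.02%.

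**Figure D2:**
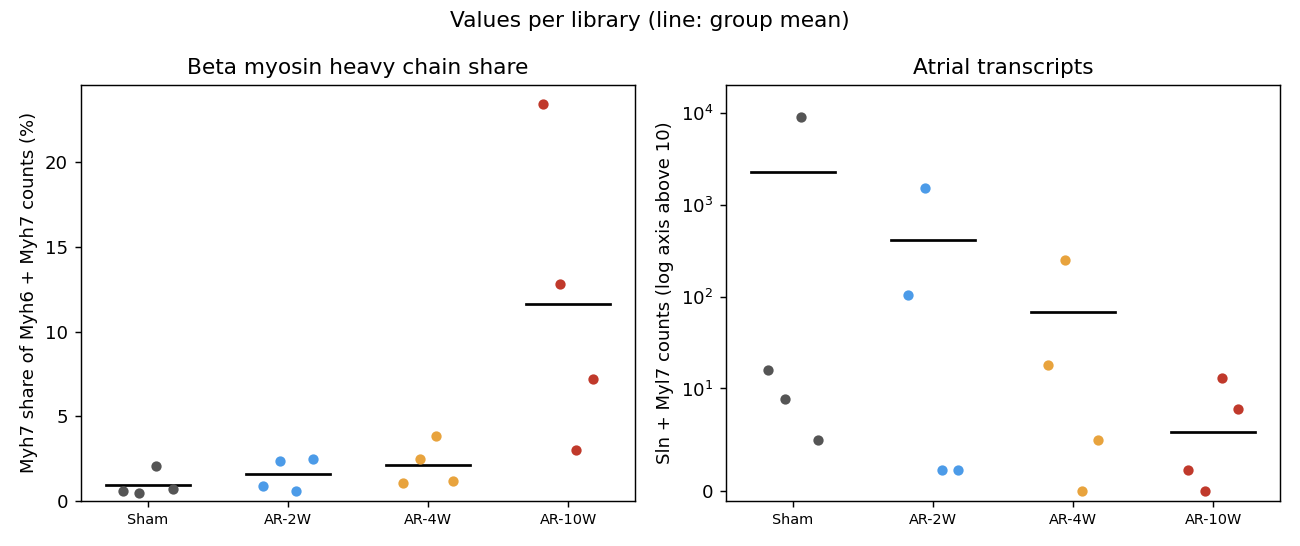
Left, Myh7 counts as a percentage of Myh6 plus Myh7 counts per library; right, Sln plus Myl7 counts per library on an axis that is logarithmic above 10. Points are libraries and lines are group means: the Myh7 share ran from 3.02% to 23.4% in AR-10W, and Sham replicate 3 held 8990 atrial counts.

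Of 17 fetal and stretch-responsive genes 12 rose, none fell and 5 were not called at 10 weeks, with Fhl1, a LIM protein, at 1.41 ± 0.28. Over the list alone 13 rose and 1 fell. The list test camera gave adjusted p = 7.73e-08, and adjusted p = 0.476 with an estimated correlation. Sham replicate 3, rich in atrial transcripts, stood at 1.06 on this list, above AR-10W replicate 3 at 0.74.

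Of 31 fatty acid oxidation genes 21 fell at 10 weeks, none rose and 10 were not called, and 25 fell adjusted over the list alone. They included Hmgcs2, the ketone body synthase (-1.59 ± 0.28), Acaa2, a thiolase (-0.99 ± 0.19), and Etfb, an electron carrier (-1.14 ± 0.19) whose exons overlap another gene. In camera the list had adjusted p = 2.99e-12, and adjusted p = 0.476 with an estimated correlation. Of 29 nuclear-encoded respiratory chain genes 19 fell and 10 were not called, for example Ndufs1 of complex I (-0.58 ± 0.11) and Cox7a1 of complex IV (-0.84 ± 0.17), and 27 fell adjusted over the list alone. For this list camera gave adjusted p = 2.99e-12, and adjusted p = 0.528 with an estimated correlation. Of 18 genes of branched-chain amino acid breakdown 12 fell and 6 were not called, among them Ppm1k, the phosphatase that activates the pathway (-0.84 ± 0.18), and 16 fell adjusted over the list alone. Camera gave adjusted p = 1.22e-08, and adjusted p = 0.476 with an estimated correlation. Of 21 TCA cycle genes 9 fell and 12 were not called, including Idh3g (-0.58 ± 0.11) and Sdha (-0.61 ± 0.13), and 15 fell adjusted over the list alone (camera adjusted p = 1.68e-08, and adjusted p = 0.528 with an estimated correlation). Among 13 mitochondrially encoded genes 5 fell, such as mt-Nd2 (-0.61 ± 0.15), 8 were not called, and 8 fell adjusted over the list alone (camera adjusted p = 1.42e-06, and adjusted p = 0.476 with an estimated correlation). On the fatty acid oxidation list the AR-10W libraries stood at -0.90, -0.39, -0.57 and -0.66, and Sham replicate 3 at -0.39. On the TCA cycle list Sham replicate 3 stood at -0.30, below AR-10W replicates 2 and 3 at -0.14 and -0.24. It also lay below them on the respiratory chain list (-0.33 against -0.21 and -0.27) and the branched-chain list (-0.27 against -0.18 and -0.26). On the mitochondrially encoded list each AR-10W library stood at -0.35 or lower, below Sham replicate 3 at -0.11. Glycolysis genes went both ways: 5 of 21 rose, among them the phosphofructokinase Pfkp (1.31 ± 0.17) and the enolase Eno1 (0.57 ± 0.08), 3 fell and 13 were not called. Over that list alone 6 rose and 4 fell (camera adjusted p = 0.220).

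Among 25 calcium handling and ion channel genes 10 fell at 10 weeks, 1 rose and 14 were not called: Kcnv2, a silent potassium channel subunit, fell by 1.61 ± 0.21, Cacna1c, the L-type calcium channel, fell by 0.45 ± 0.09, and Scn5a, the cardiac sodium channel, rose by 0.58 ± 0.12. Over the list alone 13 fell and 1 rose (camera adjusted p = 9.94e-05, and adjusted p = 0.528 with an estimated correlation). Sham replicate 3 stood at -0.24 on this list, below AR-10W replicate 2 at -0.21 and level with replicate 3 at -0.24. AR-10W replicates 1 and 4 stood lower, at -0.62 and -0.41. Of 20 tested renin-angiotensin-aldosterone and adrenergic genes 2 rose, 4 fell and 14 were not called. The alpha-1 adrenergic receptors Adra1b (-1.10 ± 0.20) and Adra1a (-1.15 ± 0.23) fell, and Ace, the angiotensin-converting enzyme, rose by 1.16 ± 0.26. Over that list alone 7 rose and 6 fell (camera adjusted p = 0.966).

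Of 35 collagen and matrix structural genes 13 rose at 10 weeks, none fell and 22 were not called, with Fbln2, fibulin 2, at 1.34 ± 0.27 and Col4a1 at 0.67 ± 0.15. Over the list alone 19 rose and 1 fell (camera adjusted p = 3.17e-07, and adjusted p = 0.583 with an estimated correlation). Col1a1 (0.88 ± 0.36) and Col3a1 (0.93 ± 0.34), the main fibrillar collagens, were not called (edgeR adjusted p = 0.115 and 0.0779). Of 34 matricellular and matrix-modifying genes 14 rose and 20 were not called, among them Ccn1 (0.86 ± 0.18) and P4ha1, a collagen hydroxylase (0.86 ± 0.19). Over the list alone 20 rose and 1 fell (camera adjusted p = 2.08e-07, and adjusted p = 0.555 with an estimated correlation). Postn rose by 2.90 ± 0.76 (edgeR adjusted p = 0.0227) and Ccn2 by 1.83 ± 0.53 (edgeR adjusted p = 0.0337). Sham replicate 3 stood at 1.05 on the collagen list, above AR-10W replicates 2, 3 and 4 at 0.24, 0.46 and 0.96. On the matricellular list it stood at 1.13, above AR-10W replicates 2 and 3 at 0.24 and 0.75.

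Among 11 Schwann cell and neuronal markers 5 fell at 10 weeks, 1 rose and 5 were not called: Kcna1, a potassium channel of myelinated axons, fell by 3.17 ± 0.36 and Plp1, a myelin protein, fell by 1.53 ± 0.23. Adjusted over the list alone the counts were again 5 and 1 (camera adjusted p = 0.00356, and adjusted p = 0.476 with an estimated correlation), and the 4 AR-10W libraries stood between -0.80 and -0.63. Of 8 T, NK and B cell markers 2 rose, Igkc and Cd79a of B cells (1.96 ± 0.53), and 6 rose adjusted over the list alone (camera adjusted p = 0.000487, and adjusted p = 0.476 with an estimated correlation). Of 19 macrophage markers 2 rose, Trem2 (1.33 ± 0.25) and the complement gene C1qa (0.70 ± 0.20), as did 2 adjusted over the list alone (camera adjusted p = 0.00927, and adjusted p = 0.615 with an estimated correlation). Of all tested genes 12.7% were called at 10 weeks. On the macrophage list AR-10W replicate 2 stood at -0.14, below Sham replicates 2, 3 and 4 at -0.12, 0.20 and 0.19. The other AR-10W libraries stood between 0.38 and 0.71.

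**Figure D3:**
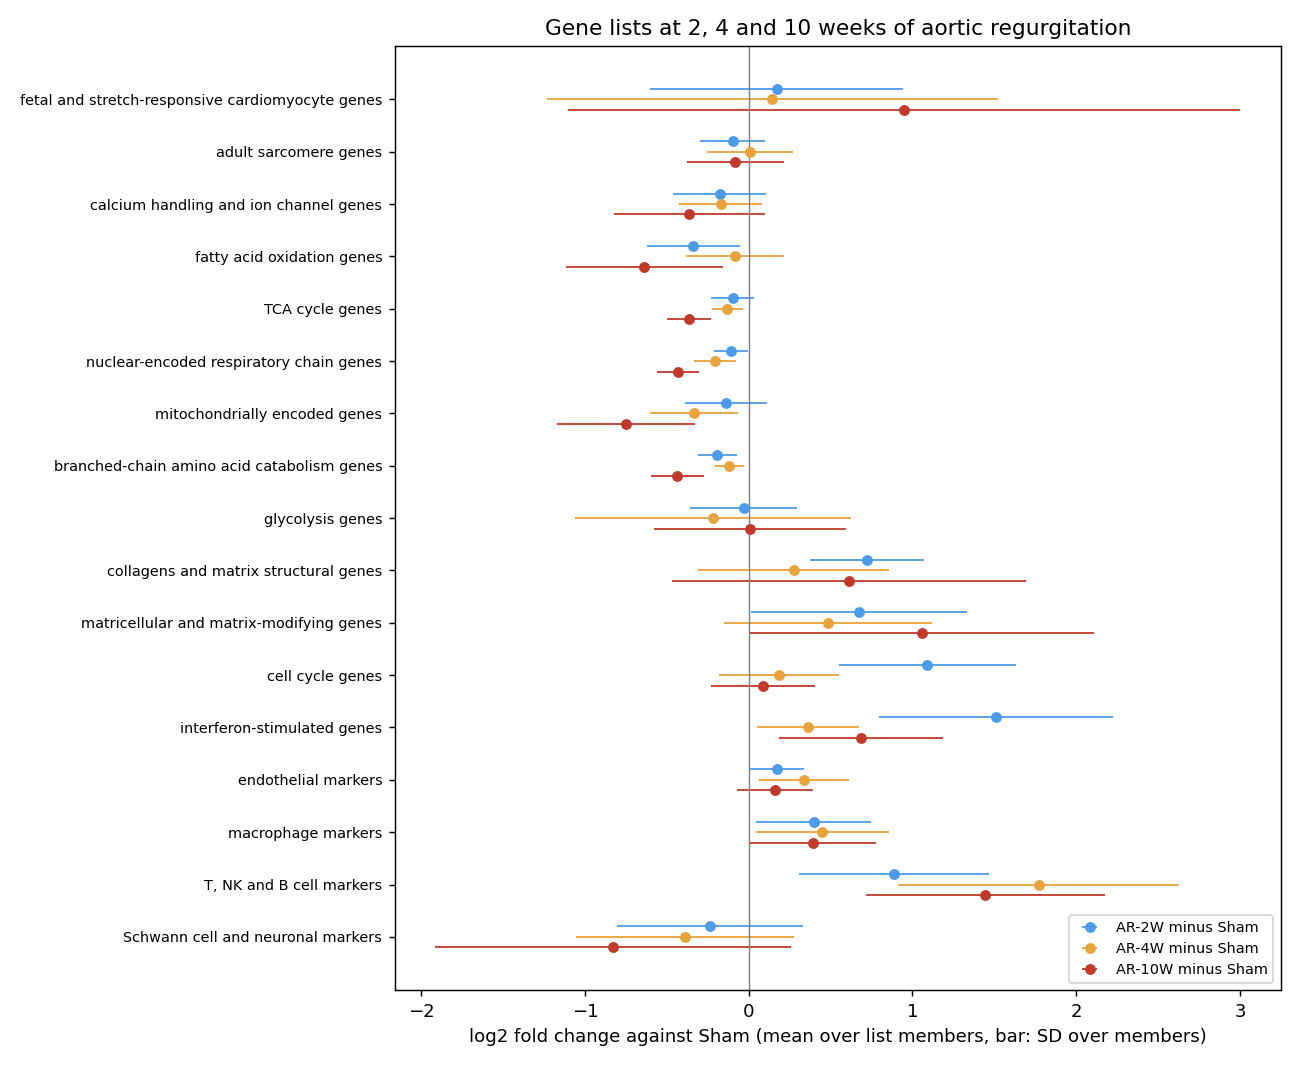
Mean log2 fold change against Sham of the tested members of 17 gene lists at 2, 4 and 10 weeks; bars are the SD over members, not an error of the mean. Fatty acid oxidation genes averaged -0.34, -0.09 and -0.64 at the 3 weeks, and interferon-stimulated genes 1.51, 0.36 and 0.69. The interferon values differed between libraries of a group. In order of replicate, the list means were 2.24, 2.04, 0.01 and 0.32 in AR-2W, and 0.20, -0.14, 1.09 and 1.12 in AR-10W.

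The 1894 calls at 10 weeks became 750, 967 and 928 without Sham replicates 1, 2 and 4, and 729 and 823 without AR-10W replicates 1 and 4. Without Sham replicate 3 the count was 2713, within 1.5 times, and without the 3 libraries rich in Sln and Myl7, chosen after the data were seen, 1327 genes rose and 1209 fell. Of the 26 genes called among the largest changes under the naming rule and the 12 chosen beforehand, 20 stayed called whichever library was left out. The exceptions were Nppa, Acta1, Postn, Ccn2, Atp2a2 and Retnla. Nppa was not called without Sham replicate 1, 2 or 4, AR-2W replicate 1, 2 or 4, AR-4W replicate 2, or AR-10W replicate 1 or 4. Acta1, Postn and Ccn2 were not called without Sham replicate 1, 2 or 4 or AR-10W replicate 1 or 4, and Acta1 also not without AR-10W replicate 2. Atp2a2 was not called without Sham replicate 1 or 2 or AR-10W replicate 1 or 4, and Retnla not without Sham replicate 2 or AR-10W replicate 1 or 4.

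From 2 to 4 weeks Pdk4, the kinase that turns glucose oxidation down, rose from 319 ± 92.3 in AR-2W to 1076 ± 576 CPM in AR-4W (mean ± SD, n = 4), a log2 fold change of 1.75 ± 0.37 (SE, edgeR adjusted p = 0.0278). Scd4, a fatty acid desaturase of a family of near-identical copies, rose by 2.86 ± 0.51 (edgeR adjusted p = 0.0118), and Txnip, a glucose-responsive arrestin, rose by 1.52 ± 0.30 (edgeR adjusted p = 0.0203). Nr4a3 fell by 2.58 ± 0.40 (edgeR adjusted p = 0.00474), Nr4a1 fell by 2.49 ± 0.40 (edgeR adjusted p = 0.00656) and Tfrc, the transferrin receptor, fell by 1.78 ± 0.31 (edgeR adjusted p = 0.0101). In all, 172 genes rose and 118 fell, and the other largest changes that met the naming rule were Neb (1.91, nebulin), Igkc (1.61), Plekhh1 (-1.91, a scaffold protein) and Atf3 (-1.75, a stress transcription factor).

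Of 25 immediate early genes 5 fell from 2 to 4 weeks and 20 were not called, with Fosb, an AP-1 subunit, at -2.13 ± 0.47. Over the list alone 10 fell and 1 rose (camera adjusted p = 3.63e-06, and adjusted p = 0.923 with an estimated correlation). Of 31 fatty acid oxidation genes 4 rose, Hmgcs2 (1.30 ± 0.27), Pdk4, Cpt1a, the enzyme of mitochondrial fatty acid entry (0.76 ± 0.18), and Cd36, a fatty acid receptor (0.47 ± 0.11), as did 4 adjusted over the list alone (camera adjusted p = 0.0133, and adjusted p = 0.961 with an estimated correlation). Of 20 oxidative stress genes 3 rose, including Cat, catalase (0.50 ± 0.07), and Nqo1, a quinone reductase (0.61 ± 0.10), and 5 rose adjusted over the list alone (camera adjusted p = 0.00880, and adjusted p = 0.600 with an estimated correlation). None of 28 interferon-stimulated genes was called and 19 fell adjusted over the list alone (camera adjusted p = 3.91e-06, and adjusted p = 0.961 with an estimated correlation). Their list mean difference of -1.14 became 0.19 without AR-2W replicates 1 and 2.

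The 290 calls between 2 and 4 weeks became 69, 77, 152 and 112 without AR-2W replicates 1 to 4. They were 65, 76, 104 and 498 without AR-4W replicates 1 to 4, and 186 without Sham replicate 2. Without the 3 libraries rich in Sln and Myl7, 20 genes rose and 16 fell, and without AR-2W replicates 1 and 2, also chosen after the data were seen, 3 rose and 8 fell. Of the 10 genes with the largest changes under the naming rule, Scd4, Nr4a3, Nr4a1 and Tfrc stayed called whichever library was left out, and Nr4a3, Nr4a1 and Tfrc without the 3 libraries rich in Sln and Myl7.

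From 4 to 10 weeks Pdk4 fell by 1.78 ± 0.37 (edgeR adjusted p = 0.0206), from 1076 ± 576 to 314 ± 87.2 CPM (mean ± SD, n = 4), and Hmgcs2 fell by 2.04 ± 0.28 (edgeR adjusted p = 0.00708). Nmrk2 rose by 2.77 ± 0.49 (edgeR adjusted p = 0.0105), Gdf15, a stress-induced hormone, rose by 2.54 ± 0.59 (edgeR adjusted p = 0.0294), and Tfrc rose by 2.05 ± 0.31 (edgeR adjusted p = 0.00708). Kcna2 fell by 2.65 ± 0.38 (edgeR adjusted p = 0.00708) and Myh7 rose by 2.30 ± 0.58 (edgeR adjusted p = 0.0444). In all, 217 genes rose and 235 fell, and the other largest changes that met the naming rule were Nr4a3 (1.93), Scml4 (1.44, a chromatin protein), Acot1 (-1.76) and Clec7a (-1.41, a fungal-sensing receptor).

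Of 27 integrated stress and unfolded protein response genes 5 rose from 4 to 10 weeks and 22 were not called. They included Manf, a secreted survival factor of the endoplasmic reticulum (0.93 ± 0.14), and Hspa5, its main chaperone (0.57 ± 0.13). Over the list alone 12 rose and 1 fell (camera adjusted p = 2.07e-06, and adjusted p = 0.356 with an estimated correlation). Of 31 fatty acid oxidation genes 4 fell, among them Ucp3, an uncoupling protein (-1.89 ± 0.44), and 19 fell adjusted over the list alone (camera adjusted p = 1.29e-11, and adjusted p = 0.638 with an estimated correlation). Of 16 endothelial markers 2 fell, Cldn5 (-0.83 ± 0.13) and Fabp4 (-0.61 ± 0.12), as did 2 adjusted over the list alone (camera adjusted p = 0.0131, and adjusted p = 0.638 with an estimated correlation). Of 11 Schwann cell and neuronal markers 2 fell, Kcna1 (-2.18 ± 0.37) and Plp1 (-1.01 ± 0.23), and 4 fell adjusted over the list alone (camera adjusted p = 0.0208, and adjusted p = 0.638 with an estimated correlation).

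The 452 calls between 4 and 10 weeks became 82, 261, 149 and 700 without AR-4W replicates 1 to 4, and 123, 721 and 71 without AR-10W replicates 1, 3 and 4. Without the 3 libraries rich in Sln and Myl7, chosen after the data were seen, 99 genes rose and 147 fell. Of the 10 genes with the largest changes under the naming rule, Nmrk2, Tfrc, Kcna2 and Hmgcs2 stayed called whichever library was left out, and all but Clec7a without those 3 libraries.

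Of the genes called at 2 weeks 54 changed the same way at 10 weeks (22 higher, 32 lower) and 1 the opposite way, and of those called at 4 weeks 129 did (69 higher, 60 lower). The weeks 2 and 4 shared 7 higher and 4 lower. Independent lists of these sizes would share 2.03 and 2.73, 7.27 and 7.42, and 0.26 and 0.32 genes. Simulated unchanged groups, set against a shared simulated Sham group, shared 0. Few calls can arise where no gene changes, so that 0 sets no benchmark for the shared calls. With the Sham libraries split into 2 and 2, the mean number shared over 6 splits was 2.67, 5.83 and 0.667. The covariance of log2 fold changes was 0.110 for weeks 2 and 10, 0.125 for weeks 4 and 10 and 0.0705 for weeks 2 and 4. Simulated unchanged groups, drawn without library-wide structure, gave 0.0359, 0.0358 and 0.0366, and the Sham splits gave means of 0.0446, 0.0517 and 0.00752. For weeks 2 and 4 the 6 splits ran from -0.0198 to 0.0272, on both sides of 0, and the correlation was 0.513 against 0.506 in simulated unchanged groups. The correlation was 0.597 against 0.506 for weeks 2 and 10, and 0.661 against 0.502 for weeks 4 and 10. The genes called in all 3 comparisons, named after their values were seen, were Fuca2, Coro1b, Fabp5, Atp8b2, Ppic and Ctla2a, all higher, and Foxn3, Dnajb9 and Ano10, all lower.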

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

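Of 215 sets of 4 libraries tested for a value far from the other 3, 15 (6.98%) held one, where chance gives about 1 in 20 (10.75). The number given for each is the gap to the nearest library divided by the range of the group. Sham replicate 3 stood apart by a lower share of mitochondrially encoded counts (0.930), a lower share of counts in the 10 most abundant genes (0.855), a higher beta myosin share (0.868) and more Sln plus Myl7 counts (0.999). It also stood apart for Myh6, the alpha myosin heavy chain (0.916), Postn (0.846) and the adaptor gene Plekhb1 (0.860). Sln plus Myl7 counts set AR-2W replicate 2 (0.932) and AR-4W replicate 2 (0.928) apart too. The other genes were E2f1 in Sham replicate 1 (0.885), Eln (0.932) and Sparc (0.856) in AR-2W replicate 2, Nppb in AR-4W replicate 1 (0.864), Acta1 in AR-10W replicate 3 (0.929) and Adam23 in AR-10W replicate 4 (0.846).

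Differences between weeks were tested directly in edgeR. Effects differed for 290 genes between 2 and 4 weeks and for 452 genes between 4 and 10 weeks, and Myh7 differed by 2.30 log2 units between 4 and 10 weeks.

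Other splits of the 8 libraries of a comparison into 4 and 4 were tried, 35 in each. The real split gave the most calls for AR-4W minus Sham (232 against at most 62 in another split), AR-10W minus Sham (1894 against 1664), AR-4W minus AR-2W (290 against 5) and AR-10W minus AR-4W (452 against 57). That is 1 of 35 splits, the smallest share that 35 splits can give (0.0357 after adjustment over the 5 comparisons). It argues against chance but cannot exclude it, and for AR-10W minus Sham another split came close to the real one. For AR-2W minus Sham chance stays open, as 2 of 35 splits reached 75 calls, the real one and one with 241. The latter set Sham replicate 3 and AR-2W replicates 1, 2 and 4 against the rest, and the one with 1664 calls set Sham replicate 3 and AR-10W replicates 1, 3 and 4 against the rest. Both point to a structure of the samples around Sham replicate 3.

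The first pattern weighed was the atrial transcripts of Sham replicate 3, and the tests on atrial genes were chosen after the result was seen. Of 14 atrial genes 13 were higher in Sham replicate 3 than in every other Sham library, from Myl4, an atrial light chain, with 488 against at most 1.73 CPM, to Nr2f2, a transcription factor, with 11.2 against 10.3, but this count restates the pattern and leaves atrial tissue in the piece of heart taken open. A regurgitation heart labelled as Sham stays open too: no AR library had more than 1519 Sln plus Myl7 counts against 8990, yet AR-2W replicate 2 and AR-4W replicate 2 came next after it, so these counts do not decide. Nor do other genes, where Sham replicate 3 lay 0.626 of the way from the other Sham libraries to AR-2W (95% interval 0.568 to 0.707, the highest of 3), 0.520 to AR-4W (0.481 to 0.570) and 0.575 to AR-10W (0.554 to 0.593). These genes were picked by calls against the other Sham libraries, which can by itself move a left-out Sham library toward the AR group. The other Sham libraries lay at most 0.166, 0.110 and 0.0922 of the way, but they had been used to pick the genes. The 95% intervals in this section come from resampling genes, so they do not measure the spread between libraries. No biological explanation was tested, since the design gives none within Sham.

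The second pattern was the interferon-stimulated genes of AR-2W replicates 1 and 2, and both tests were chosen after the result was seen. These libraries exceeded replicates 3 and 4 by a median of 2.04 log2 units. More leukocytes of every kind in those samples are argued against as the whole cause. Together, 36 leukocyte markers differed by a median of only 0.369 (95% interval 0.156 to 0.495). The lists behind this median went both ways. Monocyte and neutrophil list means were 0.92 and 0.66 in replicates 1 and 2, and 0.18 and -0.59 in replicates 3 and 4. Macrophage means were 0.62 and 0.60 against 0.16 and 0.19. Those of T, NK and B cells were 0.52 and 0.45 against 1.12 and 0.76. More of single leukocyte types stays open. A response to 2 weeks of regurgitation cannot be told apart from some other cause: 3 of 4 AR-2W libraries lay above every Sham library. An infection or another exposure of those hearts was not tested.

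The last pattern was the lower expression of 99 mitochondrial metabolism genes at 10 weeks (median -0.43), and the tests of the share of cardiomyocyte RNA and of single libraries were chosen after the result was seen. A first test of a lower share of cardiomyocyte RNA decided nothing, as adult sarcomere genes had a median of 0.0464 (95% interval -0.325 to 0.0951). A second test, picked once its values were known, used Schwann cell and neuronal markers, which such a lower share would raise. Their median was -0.873 (-1.53 to -0.00139), with an upper bound only just below 0. Fibroblast markers had 0.24 (0.09 to 0.59), endothelial markers 0.16 (0.07 to 0.24), macrophage markers 0.36 (0.21 to 0.57) and T, NK and B cell markers 1.63 (0.45 to 2.10), the direction a lower share would give. Intervals of the pericyte and smooth muscle list and the mast cell list spanned 0. The lists went both ways and the Schwann list was picked on its values, so a lower share stays open. Growth or loss of single cell types stays open too. Gene length or GC content is argued against by a median of -0.452 after a fit on both. In AR-10W replicates 2 and 3 the median difference from Sham was -0.238 (-0.272 to -0.210). As that interval does not cover the spread between libraries, it cannot decide whether AR-10W replicates 1 and 4 alone carry the pattern. A response to 10 weeks of regurgitation stays open.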

How the results depend on the processing

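DESeq2 size factors, voom, the stricter filter and library sizes without mitochondrially encoded genes left every count of calls within 1.5 times. The DESeq2 Wald test called 427, 677, 692 and 995 genes for AR-2W minus Sham, AR-4W minus Sham, AR-4W minus AR-2W and AR-10W minus AR-4W, and retained 74 of 75, 227 of 232, 289 of 290 and 449 of 452 calls. With it the weeks 2 and 4 shared 60 calls, 2 and 10 shared 219, and 4 and 10 shared 330. In edgeR, the means over Sham splits, which use fewer samples, were 0.667, 2.67 and 5.83, against 11, 54 and 129 with all Sham libraries. No filter gave 165 calls at 2 weeks. Only the 8 libraries compared, with fewer samples, gave 26, 56 and 758 calls against Sham and 72 for AR-10W minus AR-4W. The cause was not tested for the DESeq2 test or the filter.

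Other settings were added after seeing the data. Without the 3 libraries with over 200 Sln plus Myl7 counts there were 25, 22, 36 and 246 calls for AR-2W minus Sham, AR-4W minus Sham, AR-4W minus AR-2W and AR-10W minus AR-4W, and without the 4 with over 100 there were 1, 10, 5 and 190, with 24 list tests at 2 weeks. The Sln plus Myl7 covariate gave 185, 442, 2852 and 806 calls against Sham at 2, 4 and 10 weeks and for AR-10W minus AR-4W. Without AR-2W replicates 1 and 2 there were 4, 122 and 11 calls for AR-2W minus Sham, AR-4W minus Sham and AR-4W minus AR-2W. The mean of the interferon list in AR-4W minus AR-2W reversed to 0.14 without the 4 libraries and 0.19 without those 2. The cause was not tested.

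With a replicate block the calls were 10, 53, 1259, 124 and 226 in the order of the comparisons. The numbers do not pair the samples: residual correlations of same-number pairs ran from -0.46 to 0.28, 4 of 24 were over 0.1, and 1 of 16 libraries correlated best with its own number.

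Leaving out 1 library at a time gave 1 to 265 calls at 2 weeks, 10 to 469 at 4 weeks, 729 to 2713 at 10 weeks, 65 to 498 for AR-4W minus AR-2W and 71 to 721 for AR-10W minus AR-4W. List tests called ran over 12 to 22, 13 to 21, 18 to 24, 9 to 16 and 15 to 23 of 45, and camera with an estimated correlation called 0 in each. The beta myosin share difference ran from 6.75 to 13.5 at 10 weeks, 0.325 to 0.988 at 2 weeks, 0.628 to 1.57 at 4 weeks, 0.0049 to 0.942 for AR-4W minus AR-2W and 5.55 to 12.3 for AR-10W minus AR-4W.

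Over all alternatives, 11163 values of named genes stayed the same, 1252 were weaker, 405 stronger and 0 reversed. A change of sign counted as reversed only where the gene was called in the main or the alternative fit. Genes called in neither fit count among those that stayed the same, whatever their sign. For gene lists 2063 stayed the same, 200 were weaker and 2 reversed. At the depth of these libraries, 14947 of 54532 genes passed the filter.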

Other observations

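Some cytoskeleton genes were also called, on lists made after the data were seen, so that tests of these lists as wholes carry no weight and none passed with an estimated correlation in camera. Of 12 tubulin genes 8 rose in AR-10W minus Sham and 4 were not called (edgeR quasi-likelihood), with Tuba1c at 0.70 ± 0.12 (SE, n = 4) and Tubb2a at 0.77 ± 0.15. From 2 to 4 weeks 3 tubulin genes fell and all 12 had negative fold changes, and from 4 to 10 weeks 6 rose. Tubulins are close paralogs, so how reads were shared among them is uncertain. Of 16 actin-regulating genes 12 rose at 10 weeks and 4 were not called, among the former Pfn1, profilin (0.32 ± 0.08), and Arpc1b of the Arp2/3 complex (0.60 ± 0.16). At 2 weeks 4 of them rose, and from 2 to 4 weeks 4 fell and all 16 had negative fold changes. These genes were named after their values were seen.

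Other added lists had these calls at 10 weeks, where 12.7% of all tested genes were called. Of 20 lysosomal genes 6 rose and 1 fell, of 11 iron genes 1 rose and 2 fell, of 16 proteasome genes 2 fell, of 15 cholesterol synthesis genes 1 rose and 1 fell, of 16 peroxisomal genes 1 fell, and of 16 mitochondrial ribosomal protein genes none was called.

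A hypothesis of this re-analysis is that feeding state or hour of collection differed between the weeks, because Pdk4 and Txnip, which rose from 2 to 4 weeks, respond to both, and Pdk4 fell from 4 to 10 weeks. The prediction was written before the values of a second list of 11 fasting-responsive genes, Pdk4 and Txnip left out, were seen. The median of that list was 0.387 for AR-4W minus AR-2W and -0.353 for AR-10W minus AR-4W, the directions the hypothesis needs. Both comparisons contain AR-4W, with opposite signs, so a shift of that group alone would give such a pair. The medians are therefore not independent of each other. Against Sham the list had medians of -0.345, -0.158 and -0.469 at 2, 4 and 10 weeks, so AR-4W was not above Sham. Only 2 of its genes rose and 2 fell in these comparisons, the list passed in camera at the preset correlation (adjusted p = 0.00221 and 0.00235) but had adjusted p = 0.191 and 0.170 with an estimated correlation, and regurgitation itself could move the same genes. None of 19 circadian clock genes, on a list fixed beforehand, was called in either comparison (camera adjusted p = 0.362 and 0.365). Adjusted over that list alone, 6 rose and 3 fell from 2 to 4 weeks, and 2 rose from 4 to 10 weeks. Feeding and hour of collection are not given in the sources used here.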
